A study of Aspergillus terreus with 6 samples.

How the data were processed

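RNA-seq was done on mycelia of a wild-type strain of the filamentous fungus Aspergillus terreus, harvested on day 2 of shaken fermentation culture. The labels' protocols give TRIzol extraction of total RNA and libraries made with a NEBNext Ultra RNA kit. The 6 libraries fall into a control group (n = 3) and a metal group (n = 3), taken from the sample titles. The metal label names 0.25 g/L zinc sulphate and 0.40 g/L iron sulphate. The control label reads as untreated and names 0.15 g/L zinc sulphate and 0.16 g/L iron sulphate, and does not say whether these smaller amounts were in the control medium. The treatment protocol in the same labels speaks of taurine in place of metal salts, so the treatment is described here only as far as the sample labels give it. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

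The authors deposited a table of whole-number counts per gene and a table of FPKM values (fragment counts scaled by gene length and library depth) for the same 6 libraries. The submitters' processing notes name TopHat2 and DESeq. The program that counted reads, the genome build, the gene annotation, the strand setting and the way FPKM was computed are not given in the sources used here. Each deposited table holds 11680 features, of which 10784 carry an annotation-style identifier and 896 carry an identifier that marks a new gene. There were 0 columns of other samples. Total counts per library ran from 25097838 to 35124387, and the number of features with at least 1 count ran from 10366 to 10751. Where a gene had 200 or more counts in every library (6040 genes), 99.7% of the FPKM values equalled the count divided by one length per gene and one factor per library, within a tolerance of 1%; genes with fewer counts were not checked in this way. The implied gene length had a median of 1885 bases.

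The identifiers in the files were compared with the locus tags, accessions and synonyms of the 10551 genes of strain NIH2624 (assembly ASM14961v1), and 0 of the 11680 matched. The files do not pair their identifiers with gene names, products or positions. The 35 gene lists fixed before the data were examined, among them the itaconate cluster, metal uptake and central carbon metabolism, therefore had no members to test, and no gene of these pathways is named. For the same reason at most 2 identifiers that were higher and 2 that were lower in the metal group are printed. The rule fixed in advance asked for genes past the threshold with no overlap between groups and a mean log2 CPM of 3 or more. No gene passed the threshold, so the 2 on each side with the smallest unadjusted p among genes that met the other criteria were taken, a choice made after the values were seen.

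Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: low-count genes were removed with filterByExpr, library sizes were scaled by TMM (trimmed mean of M-values), and a robust quasi-likelihood F test compared metal with control, without a block. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM (library-scaled counts) values were scaled by TMM. Distances between libraries are root mean square differences of log2 CPM with a prior count of 2. The alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, 3 other filters, DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, each library and each replicate number left out in turn, removal of the 10 most abundant genes, a threshold of 0.01 with a change of at least 2-fold, and limma on log2(FPKM + 1), with a pseudocount of 0.1 and a minimum mean FPKM of 1 as variants. Leaving out control replicate 2 changed the outcome, so that fit was itself repeated under further settings, chosen after seeing the data.

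Same-numbered control and metal libraries were checked for pairing: the correlations of their deviations from the group means were 0.067, 0.16 and 0.17. These were all positive, and the values for libraries of different numbers ran from -0.29 to 0.23. That range holds the same-numbered values, so the numbers were not taken to pair the samples. The fit with the number as a block is given as an alternative. No 2 libraries were copies: in exact binomial tests over genes with 20 or more counts in a pair, between 51.5% and 77.9% of genes differed at an adjusted p under 0.05. The edgeR procedure was tested on simulated counts drawn with the means, library sizes and dispersions of the real libraries, with 200 genes changed in each of 3 runs. With the spread of all 6 libraries and 9568 genes, it recovered 14.4% of genes changed 2-fold, 72.5% of those changed 4-fold and 87.7% of those changed 8-fold, and 5.75% of its calls were false. With the spread of the 5 libraries that leave out control 2 and 9783 genes, it recovered 33.5%, 84.3% and 95.5%, and 5.80% of its calls were false. Each simulated gene was drawn independently, without a shift shared by many genes such as sets control 2 apart. The recovered shares are therefore no detection limit for the real libraries. The position of control 2 in the genes called without it was set beside simulated libraries (5 runs each) in which no gene changed, in which genes changed as fitted and control 2 was drawn as a control, or in which they did and control 2 was drawn as a metal library, taking the 1661 genes with the smallest p each time; this was added after seeing the data.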

Results

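The transcriptome of A. terreus, a fungus used for the industrial production of itaconic acid, was compared between mycelia grown with the zinc and iron salts at the amounts called optimized and control mycelia, both on day 2. The series asks how metal ions bear on itaconic acid fermentation by this species. Total counts were 31981700, 29917757 and 25097838 in controls 1, 2 and 3 and 33045516, 32607821 and 35124387 in metal libraries 1, 2 and 3. The 10 most abundant genes took between 8.95% and 12.6% of the counts of a library, and the single most abundant gene between 1.67% and 2.50%. Features marked as new genes held between 0.945% and 1.497% of the counts. After the low-count filter, 9698 genes were tested.

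The libraries did not fall into their labelled groups. Control 2 lay with the 3 metal libraries, at root mean square distances of 0.58 to 0.65 log2 units from them, against 0.50 to 0.60 between metal libraries. Its distances to controls 1 and 3 were 1.15 and 1.18, larger than any distance between controls 1 and 3 and the metal libraries (0.95 to 1.14). Controls 1 and 3 were 0.78 apart. The first principal component, with 60.2% of the variance, gave control 2 a score of 40.6, the metal libraries scores of 18.8 to 32.6, and controls 1 and 3 scores of -59.9 and -64.1. The Pearson correlation across genes of log2 CPM, over genes that are not independent replicates, averaged 0.977 between control 2 and the metal libraries and 0.920 between control 2 and the other controls. The mean of log2(FPKM + 1) correlations gave 0.991 and 0.952.

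**Figure D1:**
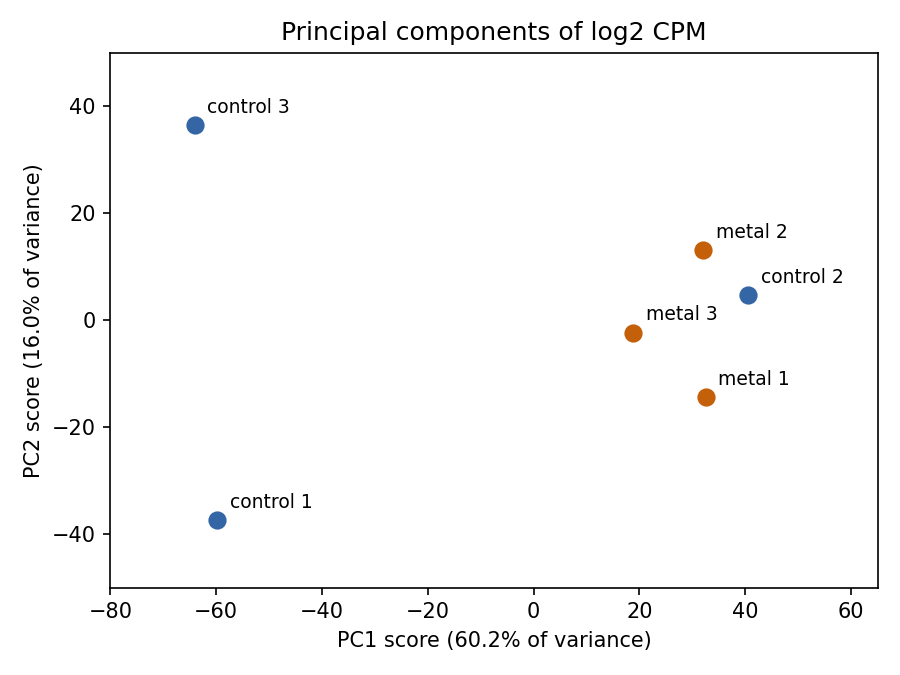
Scores of the 6 libraries on the first and second principal components of log2 CPM (x axis, 60.2% of the variance; y axis, 16.0%), with control libraries in blue and metal libraries in orange. Control 2 has a score of 40.6 on the first component, beside the metal libraries and away from controls 1 and 3.

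With the groups as labelled, no gene passed the main test. Under edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 genes rose and 0 fell, and the lowest adjusted p was 0.49. At an unadjusted p under 0.05, 180 genes were higher and 655 lower in the metal group, 835 in all, where 485 of 9698 would pass by chance. The 3 metal libraries were all above the 3 controls in 578 genes and all below them in 692, together 13.1% of the tested genes, where chance gives 10%. Both chance values are averages and give no spread for genes that vary together. Across the other splits of the libraries into 3 and 3, 27 to 1696 genes had an unadjusted edgeR p under 0.05. In those splits 290 to 2214 genes had no overlap, against 1270 in the labelled split, so neither count stands out. In fitted values, 169 genes were at least 2-fold higher and 700 at least 2-fold lower. The biological coefficient of variation was 34.1%, and the median standard error of a log2 fold change was 0.28. limma-voom also called 0 genes in either direction (309 higher and 369 lower at an unadjusted p under 0.05). The edgeR fit with the replicate number as a block gave 398 higher and 492 lower at an unadjusted p under 0.05. The size of the excess of lower genes thus depended on the test. That excess is not read as an effect of the salts. DESeq2 called 10 genes higher and 136 lower at its adjusted p under 0.05. Of these 146 genes, 139 were also tested by edgeR, and 97 of the 139 had no overlap between the groups.

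The genes with the smallest unadjusted p that met the other criteria for naming did not pass the edgeR adjustment either. They carry no name, product or position in the files, and were chosen after their values were seen. The criterion of no overlap between the labelled groups places control 2 on the controls' side of these genes by construction, so they say nothing about where that library belongs. Aterreus0G064930 was at 291 ± 77.0 CPM in the controls and 75.8 ± 14.0 CPM in the metal libraries (SD, n = 3 each), a log2 fold change of -1.94 ± 0.26 (SE) with an edgeR adjusted p of 0.49. Controls 1, 2 and 3 were at 289, 214 and 368 CPM in this gene. Aterreus0G034490 was at 308, 45.8 and 398 CPM in controls 1, 2 and 3 and at 7.86, 12.6 and 7.79 CPM in the metal libraries, a log2 fold change of -4.73 ± 0.78 (SE), with the same edgeR adjusted p of 0.49. On the other side, Aterreus0G037410 was at 39.3 ± 10.1 CPM in the controls and 96.4 ± 30.5 CPM in the metal libraries (SD, n = 3 each), a log2 fold change of 1.29 ± 0.30 (SE, edgeR adjusted p = 0.57). Aterreus0G013290 was at 10.7 ± 1.87 CPM and 18.8 ± 1.38 CPM (SD, n = 3 each), a log2 fold change of 0.81 ± 0.20 (SE, edgeR adjusted p = 0.57). DESeq2 called all 4 of them, with adjusted p-values of 7.94e-09, 1.10e-10, 0.0186 and 0.0385 in the order given here. The 4 genes were picked for small p and no overlap in these same libraries. A second test on the same counts is therefore not independent support.

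**Figure D2:**
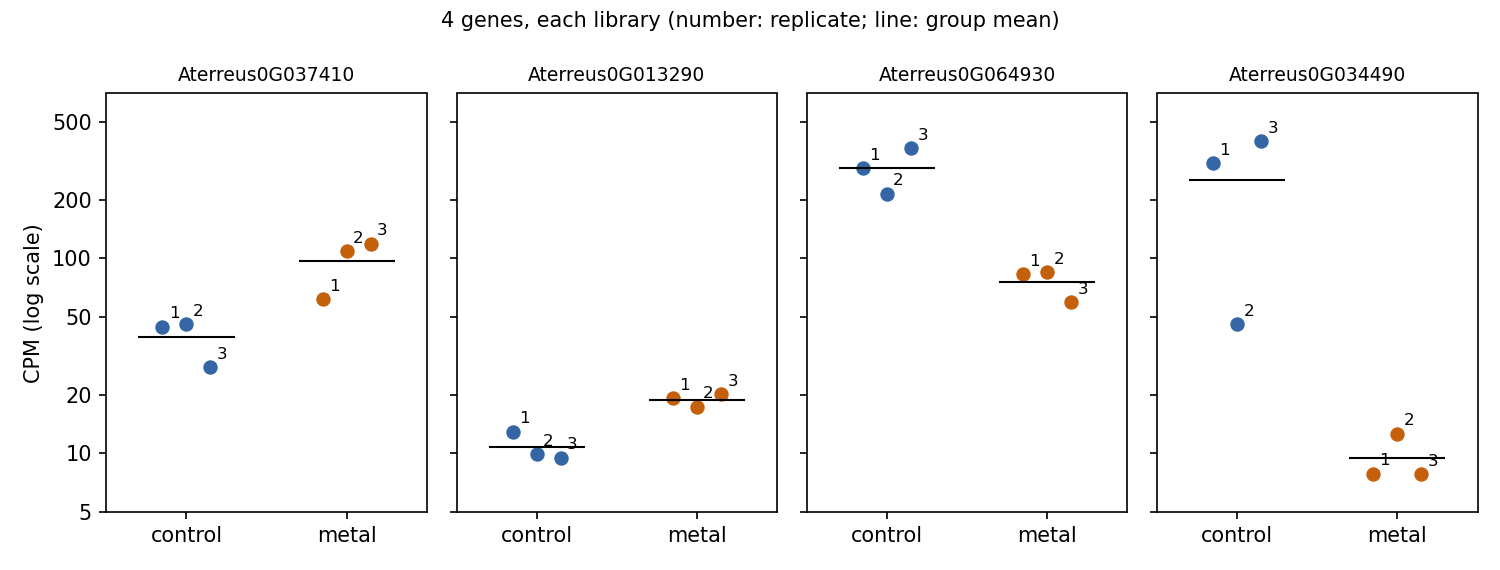
CPM on a log axis of the 4 printed genes in each control (blue) and metal (orange) library, with the replicate number beside each point and a line at the group mean. In Aterreus0G034490, control 2 (45.8 CPM) lies between controls 1 and 3 (308 and 398 CPM) and the metal libraries (7.79 to 12.6 CPM). The genes were chosen for having no overlap between the labelled groups, which places control 2 on the controls' side.

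One library decided the outcome. Without control 2, the same edgeR test called 652 genes that rose and 1009 that fell in the metal libraries against controls 1 and 3, 16.7% of the 9935 genes tested. Of these, 405 rose and 720 fell at least 2-fold and 82 rose and 314 fell at least 4-fold in fitted values. In 36 of the called genes every library of 1 group had 3 counts or fewer, so their fitted folds depend on the prior count. The median log2 fold change was 1.13 among the genes that rose and -1.42 among those that fell. The biological coefficient of variation was 24.1%, and the median standard error of a log2 fold change was 0.25. Leaving out any other single library gave 0 genes in both directions. Without control 2 and a metal library, 177 rose and 362 fell without metal 1, 236 and 465 without metal 2, and 256 and 524 without metal 3. Without controls 1 and 2, 1020 rose and 1004 fell, and without controls 2 and 3, 975 rose and 1071 fell; these fits keep 1 control and take their spread from the metal libraries alone. DESeq2 without control 2 called 1135 genes that rose and 1253 that fell, and these included 1659 of edgeR's 1661 calls, all 1659 in the same direction. All 4 printed genes passed in this comparison, with edgeR adjusted p-values of 0.00117 for Aterreus0G064930, 6.02e-05 for Aterreus0G034490, 0.0264 for Aterreus0G037410 and 0.0484 for Aterreus0G013290. Their log2 fold changes there were -2.11 ± 0.21, -5.22 ± 0.28, 1.42 ± 0.33 and 0.76 ± 0.21 (SE) in that order. The 4 genes were chosen by their p in a fit that includes these same libraries, so their passing here is not independent support. With a metal library left out as well, both genes that fell passed each time. Aterreus0G037410 then missed the threshold without metal 2 or metal 3 (edgeR adjusted p = 0.0719 and 0.0746), and Aterreus0G013290 missed it without metal 1, metal 2 or metal 3 (edgeR adjusted p = 0.136, 0.106 and 0.151). The fits that keep 1 control do not show whether a gene is stable between controls. In them the genes that fell passed, and both genes that rose missed the threshold without control 3 (edgeR adjusted p = 0.0823 for Aterreus0G037410 and 0.112 for Aterreus0G013290). This comparison rests on 2 control libraries. It was taken further because leaving out control 2 changed the outcome, and its adjusted p-values do not allow for that choice. If the label of control 2 is right, the called genes set controls 1 and 3 apart from the other libraries. They need not then be responses to the salts.

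**Figure D3:**
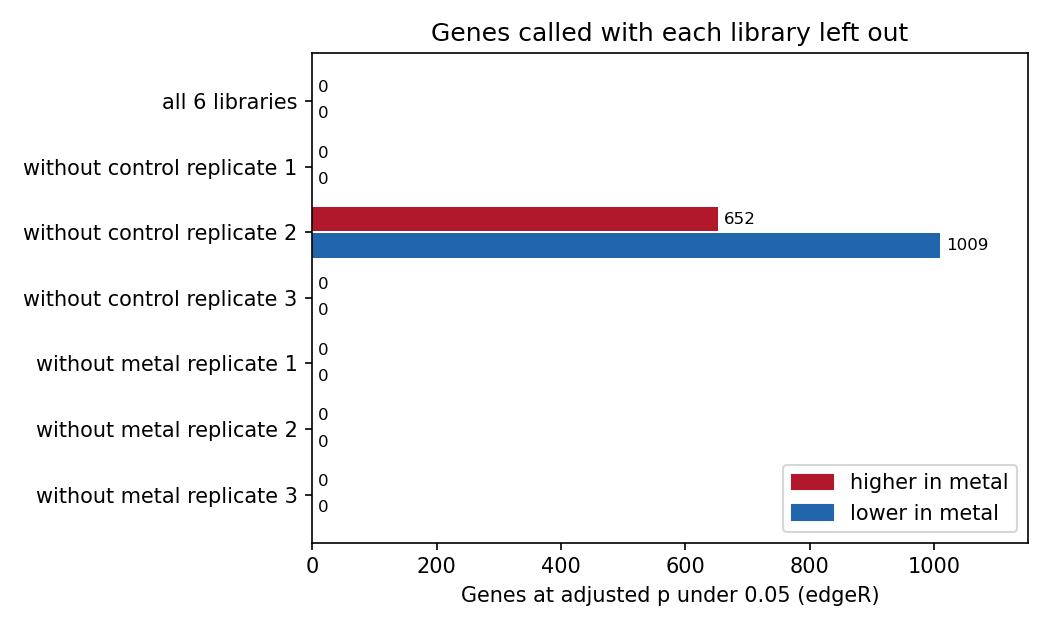
Number of genes at an edgeR adjusted p under 0.05 (x axis) that were higher (red) or lower (blue) in the metal group, with all 6 libraries and with each library left out (y axis). Only the fit without control 2 calls genes, 652 higher and 1009 lower.

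Most genes called without control 2 were annotated ones, as were most genes tested. Among features marked as new genes, 20 rose and 32 fell of 619 tested, or 8.40%, against 17.3% of the annotated genes. The 2 kinds were not matched for abundance, and calls varied with it. Among the 1987 genes of lowest mean log2 CPM, 38 rose and 142 fell. Among the 1987 of highest mean log2 CPM, 195 rose and 193 fell, so the excess of falling genes was absent there. The genes that fell held 14.97% and 15.13% of all counts in controls 1 and 3, and between 3.86% and 4.74% in the metal libraries. The genes that rose held 7.34% and 6.35% in controls 1 and 3 and between 14.0% and 14.9% in the metal libraries. These shares describe genes chosen for their difference and are not independent evidence of it.

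In the genes called without it, control 2 was mostly at the level of the metal libraries. Its counts had no part in those calls, but it was left out because the calls appear only without it. That choice favours genes in which control 2 lies away from controls 1 and 3. The simulated libraries below do not include the choice. The position of control 2 is also measured against the same controls 1 and 3 that the calls rest on. The genes that fell held 4.06% of its counts and the genes that rose 15.6%. In 628 of the 652 genes that rose and 957 of the 1009 that fell, together 95.4%, control 2 was nearer to the mean of the metal libraries than to that of controls 1 and 3 on the log2 scale. The other 24 and 52 genes had control 2 nearer to controls 1 and 3. On a scale where 0 is the mean of controls 1 and 3 and 1 the mean of the metal libraries, the median position of control 2 was 1.06 among genes that rose and also 1.06 among genes that fell. In simulated libraries with no changed gene, control 2 was nearer to the metal mean in 55.4% of the 1661 genes with the smallest p, with a median position of 0.59. With genes changed as fitted and control 2 drawn as a control, it was nearer in 9.10%, with a median position of 0.070. With control 2 drawn as a metal library, it was nearer in 92.9% (92.7% to 93.2% over 5 runs), with a median position of 0.95. The observed 95.4% and 1.06 lie above these values, on the side away from controls 1 and 3. The simulated genes were drawn independently, so the narrow range over runs leaves out shifts shared by many genes. No real metal library was held out in the same way. The small difference from a simulated metal library is therefore not interpreted.

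**Figure D4:**
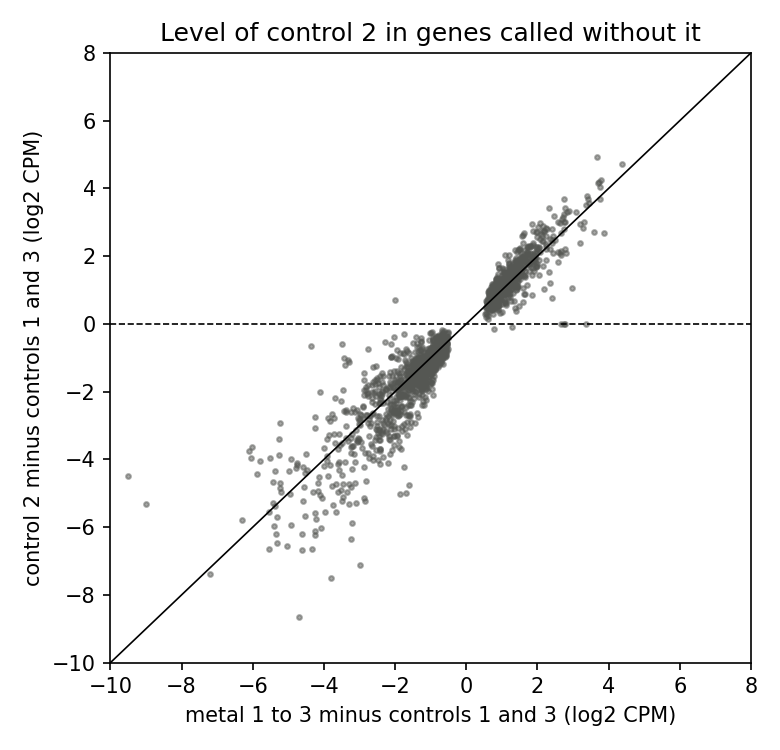
Log2 CPM of control 2 minus the mean of controls 1 and 3 (y axis) against the mean of the metal libraries minus the same mean (x axis), for the 1661 genes called without control 2 (1 point each). Points on the solid line have control 2 at the metal level and points on the dashed line have it at the level of controls 1 and 3. Measured along the y axis, 95.4% of the genes lie nearer to the solid line than to the dashed line.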

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

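With the labelled groups, edgeR called 0 genes in both directions under every other scaling and filter tried, without the 10 most abundant genes and at the stricter threshold, as did limma-voom and the 3 limma fits of FPKM values. The fit with the replicate number as a block, which shares only a number between groups, also called 0 genes rising and 0 falling. DESeq2 called 10 rising and 136 falling, and the cause of its difference from edgeR was not tested. Of these DESeq2 calls, 144 were among the genes that edgeR called without control 2. With single libraries or replicate numbers left out, the counts ran from 0 to 652 rising and from 0 to 1009 falling. They were above 0 only without control 2 (652 and 1009) and without replicate 2 of both groups (236 and 465). No printed gene changed direction. Without control 2, which was examined further only after seeing the data, DESeq2 called 1135 rising (the cause was not tested) and a threshold of 0.01 with at least 2-fold change left 134 rising and 341 falling, since fewer genes meet it. A further library left out gave 177 to 1020 rising and 362 to 1071 falling genes. The counts moved by over 1.5 times without control 1 (1020 rising; without control 1 or 3, the 1 control left is assumed to vary like the metal libraries), metal 1 (177 and 362), metal 2 (236 and 465) and metal 3 (256 and 524). A correction for the implied gene length, with which the fold changes had a Spearman correlation of 0.15 across genes, left 614 rising and 966 falling. Total-count scaling put the median log2 fold change at -0.09, against -0.0075 under TMM, and gave 524 rising and 1198 falling. The excess of the correlation of control 2 with the metal libraries over that with the other controls was 0.0576 in log2 CPM and 0.0385 in log2(FPKM + 1), a narrower scale at low values. The alternatives for gene lists and the itaconate cluster were not run because no identifier matched. In simulation at the depth and spread of all 6 libraries, 14.4% of 2-fold changes were recovered. The simulated genes varied independently, so this does not show what could be detected where control 2 shifts many genes at once.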

Other observations

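Except for the count of splits for the labelled comparison, the tests in this part were chosen after the results were seen. Genes whose identifier numbers lie next to each other changed together. Without control 2, windows of 6 tested genes in the order of the identifier numbers held 4 or more genes that fell at least 2-fold in 68 places, which form 19 separate runs, against a median of 3 and a highest value of 20 windows in 10000 permuted orders (permutation p = 1e-04, the smallest they can give). For genes that rose there were 14 windows in 7 runs, against a highest permuted value of 8 (permutation p = 1e-04). With a minimum of 4-fold, 34 windows remained for falling genes and 0 for rising genes. The longest run held 11 falling genes within 13 consecutive numbers, with a median log2 fold change of -4.15. Its median level was 582 and 996 CPM in controls 1 and 3, 12.7 CPM in control 2, and 39.4, 24.0 and 74.2 CPM in metal libraries 1, 2 and 3. The other 2 genes inside it, at adjusted p-values of 0.84 and 0.20 in edgeR, did not pass. The next longest run held 9 falling genes within 12 numbers, with medians of 238 and 188 CPM in controls 1 and 3, 9.997 CPM in control 2 and 15.5 to 25.5 CPM in the metal libraries. The longest runs of rising genes held 4 genes each.

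The files do not say that the identifier numbers follow the genome, but the fold changes can be tested against that order. With all 6 libraries, log2 fold changes of consecutive numbers had a Pearson correlation of 0.27 across 8029 pairs of genes, above the highest of 10000 permuted orders (0.048). The correlation fell to 0.13 at 2 numbers apart and 0.091 at 3 apart, and was 0.019 at 50 apart. The Spearman correlations were lower, 0.18, 0.070 and 0.048 at 1, 2 and 3 apart, so large fold changes raise the Pearson values. Reads shared by overlapping genes would act first on direct neighbours. The values at 2 apart were above the highest permuted ones, 0.13 against 0.041 for Pearson and 0.070 against 0.044 for Spearman. Reads shared within separate pairs of neighbours would not raise these values, but a gene that overlaps both of its neighbours could. Gene positions and the strand setting are not known, so shared reads stay open as a cause. A candidate explanation is that the numbers follow gene order and that groups of adjacent genes vary together. Placing the identifiers on the authors' genome would decide this and was not done. Whether the covariation is tied to the salts was not tested.

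The position of control 2 among the metal libraries leaves open what that sample is. An exchange with a metal library needs a library labelled metal that lies with controls 1 and 3. The nearest one was 0.95 log2 units from control 1 or 3, while controls 1 and 3 were 0.78 apart. The metal libraries were at most 0.60 from each other. These distances argue against an exchange, although the 0.78 rests on 1 pair of libraries. A metal library under a wrong label stays open. Where controls 1 and 3 stood at least 4-fold apart from the 3 metal libraries (156 genes), control 2 lay at least 2-fold toward them in 21; with each metal library taken in turn in place of control 2 the counts were 4 of 145, 6 of 148 and 23 of 182 for metal 1, 2 and 3, so that metal 3 alone decides whether control 2 stands out. In the genes called without it, control 2 was nearer to the metal mean in 95.4%. The share was 92.9% for a simulated metal library and 9.10% for a simulated control. These simulations draw each gene independently and leave out that control 2 was picked for its effect on the calls. They do not decide between a wrong label and a culture in that state. A control culture that had reached the expression state of the metal cultures cannot be told apart from a wrong label: 1270 genes separated the labelled groups without overlap, against 1541, 1314 and 2214 when metal 1, 2 or 3 took the place of control 2, which shows no excess for the labelled split but would also follow if the salts had little effect.

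The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The labelled split called 0 genes, and so did all 10 (highest other, 0), which says nothing about chance because no split can call fewer. At an unadjusted p under 0.05, the labelled split gave 835 genes and 4 of the 10 splits gave as many, the highest other 1696. The 3 other splits of these 4 keep controls 1 and 3 together with 1 metal library, which points to the structure of the samples. The 5 libraries without control 2 can be split into 2 and 3 in 10 ways, again too few for a share under 0.05. The labelled split called 1661 genes and was the 1 that called any (highest other, 0). That set of libraries was taken up because its labelled split called genes, so this result is no separate support.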
